A study of Mus musculus with 2 samples.

How the data were processed

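Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in mouse hematopoietic stem cells sorted from wild-type bone marrow. Per the labels, about 1000 cells entered each library. The cells had been transduced with an empty MSCV retrovirus (control) or with MSCV carrying H1C, the linker histone gene now named H1f2 (H1C). There were 2 libraries, 1 per group, and the group of each was taken from its treatment label.

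Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Bowtie2 2.2.9, Picard, MACS2 and featureCounts, and the build was mm10. The role and settings of each tool, the treatment of duplicate reads and any shift of reads to the transposase cut site were not given in the sources used here. Reads kept as duplicates, or not shifted, would alter summit heights and positions. Each library had its own deposited list of accessible regions, so regions had been called per sample and not on pooled samples.

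In each deposited list the fold is a ratio of the summit pileup to the local background of the same library, with 1 added to each. The deposited −log10 p and −log10 q values are those of the authors' peak caller, and the lowest −log10 q was 1.31 in control and 1.34 in H1C. The deposited score equalled the whole part of 10 times −log10 q for 99.969% of control and 99.962% of H1C entries. These values belong to the authors' lists and were used to describe, rank or filter regions within a list.

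The lists give no read totals. The pileup (fragments or reads stacked at the summit) and the local background were therefore solved from the fold and the Poisson −log10 p. The solution was accepted where the pileup came out whole within a relative tolerance of 0.0001, which held for 32005 of 32005 control and 13155 of 13156 H1C entries. The lowest local background of a list is the genome-wide background, which is in proportion to depth. Local values above it rose in steps of 0.02 in both lists. On simulated data with known answers, the solver recovered 100% of 3148 pileups, and the comparison of the spread of pileup ratios with simulations of 1 factor called 1 of 20 data sets without and 20 of 20 with an extra spread.

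Entries on chromosomes 1 to 19, X and Y that touched or overlapped were merged into regions, and other sequences were kept apart. A region was shared when at least 1 bp overlapped a region of the other library. Chance overlap came from 100 random placements of regions within their chromosomes. Placement was uniform along each chromosome, with no allowance for gaps, poorly mapped sequence or genes. The annotation used was a RefSeq gene table of the same build, GRCm38, with the start and end of each gene. It held no strand, transcripts or exons, so the planned promoter class was replaced by regions within 1000 bp of either end of a protein-coding gene, called gene-end regions. The other classes were the rest of the gene body and the space outside protein-coding genes. Base composition and sequence motifs were not analysed here.

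With 1 library per group no test between conditions was possible, and no p-value is given. Shares have exact Clopper-Pearson 95% intervals, and ratios of pileups have exact conditional binomial 95% intervals. Both cover counting error only, since each group held 1 library. Amplified fragments are not independent molecules, so the intervals can be too narrow even for that. Ratios of H1C to control pileup were divided by the ratio of genome backgrounds. For each gene list, the kept share (genes with a control gene-end region that also had one in H1C) was set against 10000 random lists of the same size, drawn from genes with a control gene-end region and matched on 10 bins of control fold. Its median pileup ratio was placed in the same way. Such a percentile is a description of these libraries.

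The comparisons, the gene lists, the markers of other cell types and the rule for named genes were fixed before the data were examined. The rule named H1f2 and Dek, and from each list up to 3 control-only, 2 shared and 2 H1C-only genes by fold. It also named the 10 control-only and 10 H1C-only regions with the highest fold, and the top 5 shared regions of each list. Some genes that the rule named are not reported here. All listed genes matched the annotation except 1 of 25 interferon genes. The pileup comparison at strong regions (control pileup of at least 60), the class of high-copy regions (local background at least 5 times the genome background) and the count of regions within 50 kb of a gene were chosen after the data had been seen. The planned thinning of control to a shallower H1C library was replaced by scaling up at the background ratio, which was above 1, and thinning was used for the alternative ratio. Alternatives covered thresholds, overlap rules, windows, list lengths and backgrounds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.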

Results

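Accessible chromatin was compared between hematopoietic stem cells, defined by the surface phenotype CD48-CD150+LSK, that carried an empty retrovirus and cells that carried H1C. H1C is a linker histone, a protein that binds DNA where it enters and leaves the nucleosome. The series concerns DEK, a chromatin protein, and the tolerance of replication stress in Fanconi anemia, an inherited failure of DNA crosslink repair and blood formation. The comparison asks how added H1C altered open chromatin in wild-type stem cells. Each group held 1 library, so no difference below has a replicate check. The genome background was 3.99 per position in control and 4.40 in H1C, a ratio of 1.10 of H1C to control. On this measure H1C was not the shallower library. The median local background at shared summits gave a ratio of 0.872. Local background is counted in a wider window around the summit, which takes in reads of the region itself. It is therefore not an independent measure of depth.

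The H1f2 gene, at chromosome 13, 23738807 to 23739531 (mm10), was accessible in both libraries. In control a single region from 23738677 to 23740174 spanned the gene, with a summit pileup of 72 and a fold of 6.06. In H1C the span held 2 regions, with pileups of 33 and 43. The depth-scaled log2 ratio of the higher summit to control was -0.89 (95% interval -1.47 to -0.32), so reads at H1f2 were not in excess in the H1C library. Accessibility does not measure expression, so these values do not check whether H1C was expressed. Whether reads from the inserted copy would map to H1f2 was not examined. Dek, at chromosome 13, 47084767 to 47107530, had 1 region in each library over 1000 bp inside the gene, starting at 47105743, with pileups of 32 in control and 29 in H1C. Its log2 ratio was -0.28 (95% interval -1.06 to 0.49), a difference within counting error.

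The H1C library had fewer accessible regions than control, and most of those it had were also open in control. Control had 31843 regions covering 12.8 Mb and H1C had 13012 covering 4.85 Mb, 2.45 times fewer regions and 2.65 times less length. Mean width was 403 bp in control and 372 bp in H1C. Of the H1C regions, 11063 (85.0%, 95% interval 84.4 to 85.6) overlapped a control region, against 0.995% after random placement. Of the control regions, 10874 (34.1%, 33.6 to 34.7) overlapped an H1C region, against 0.409% by random placement. Uniform placement is a low baseline, here and for gene ends, and being above it does not measure how alike the libraries were. Control summit pileups thinned by the ratio of 0.872 passed the H1C cutoff at 31132 regions on average over 100 draws. At the ratio of 1.10 the number was 31741, which scaling up could hardly lower. Both counts test the summit p alone and not the width of a region, so they can overstate the number called. Median fold was 4.41 in control and 4.31 in H1C, which describes each list and does not compare them.

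**Figure D1:**
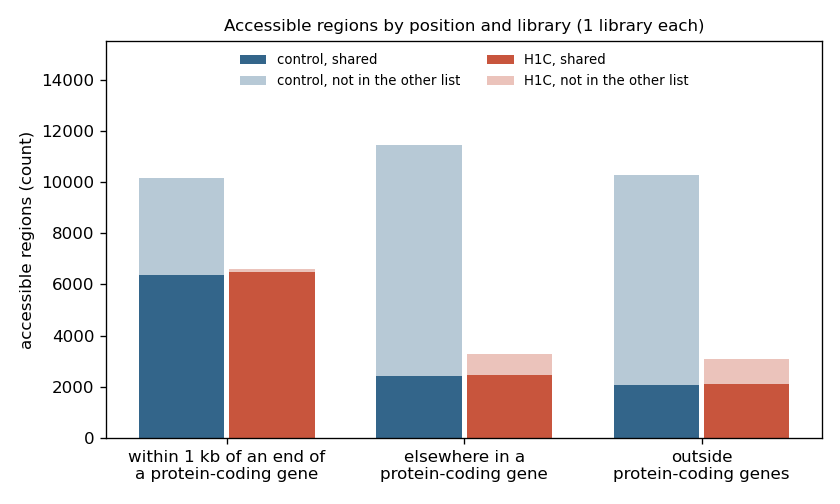
Number of accessible regions (vertical axis, count) by position relative to protein-coding genes, with blue bars for control and red bars for H1C; dark parts are shared with the other library and pale parts are not. Control exceeds H1C in every class, with 10147 against 6619 gene-end regions and 11436 against 3287 in the rest of gene bodies.

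Regions at gene ends were shared far more often than regions elsewhere. Gene-end regions made up 31.9% of control regions (95% interval 31.4 to 32.4) and 50.9% of H1C regions (50.0 to 51.7), against 3.75% and 3.71% after random placement. H1C had 1.53 times fewer gene-end regions and 3.39 times fewer other regions than control. Of the control gene-end regions 62.9% (62.0 to 63.9) were shared, against 21.0% (20.3 to 21.8) in the rest of gene bodies and 20.3% (19.5 to 21.1) outside protein-coding genes. Of the H1C gene-end regions 97.9% (97.6 to 98.3) were shared. When the same number of regions was taken from each list by −log10 p, gene-end regions made up 56.3% of control, above the H1C share.

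Strong control regions were nearly always called in H1C and weak ones rarely. The share also called in H1C rose from 8.94% of control regions with a pileup of 20 or less to 33.9% at pileups above 30 and up to 40, and to 99.8% above 80. Gene-end regions had the higher share in each step above a pileup of 20. Within bins of control pileup the difference between gene-end and other regions fell from 42.2 to 9.78 percentage points, and within bins of pileup and width to 6.40 points.

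**Figure D2:**
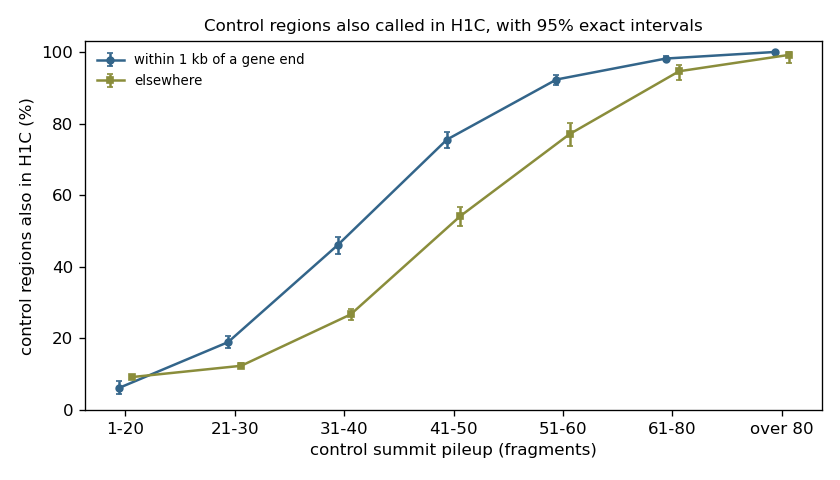
Share of control regions that overlap an H1C region (vertical axis, %) by control summit pileup (horizontal axis), for regions within 1000 bp of a gene end (blue circles) and elsewhere (green squares), with exact 95% intervals for counting error. Between pileups above 30 and up to 40, 46.0% of gene-end and 26.7% of other regions were shared.

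At strong regions pileups were lower in H1C, with similar medians in each class and chromosome and a wider spread outside protein-coding genes. Of 3688 control regions with a pileup of at least 60, leaving out high-copy regions, 3623 were shared. Their median depth-scaled log2 ratio of H1C to control was -0.92 (quartiles -1.09 and -0.76), a ratio of 0.529, and 99.2% lay below 0. The median was -0.91 at gene ends (SD 0.24, 99.97% below 0) and -0.92 outside protein-coding genes (SD 0.45, 92.3% below 0), and over 20 chromosomes with at least 33 such regions it ran from -0.98 on chromosome 14 to -0.89 on chromosome 17. High-copy regions had a median of -0.12 (quartiles -0.57 and -0.04) over 50 shared regions, of 60 in control. Choosing regions by their control pileup favours a low ratio, and the 484 strong H1C regions, all of them shared, had a median of -0.70. Scaled by the local background at shared summits, which takes in reads of the regions themselves, the median of the strong control regions was -0.58.

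**Figure D3:**
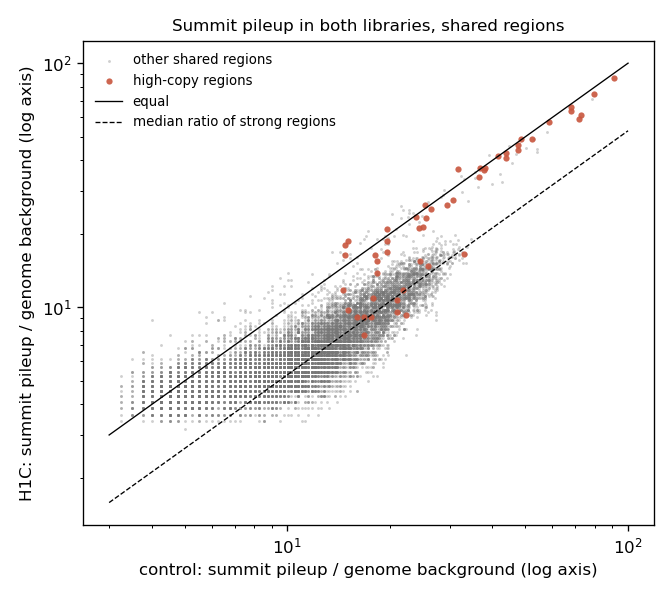
Summit pileup divided by the genome background in control (horizontal log axis) and H1C (vertical log axis), with a grey point for each shared region and red points for high-copy regions; the solid line marks equality and the dashed line a ratio of 0.529. Strong regions lie along the dashed line, and many high-copy regions lie near equality.

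Regions called in a single library lay mostly away from gene ends, except for the strongest control-only ones. Over all 20969 control-only regions, 17.9% (95% interval 17.4 to 18.5) lay at gene ends. Of the top 10 control-only regions 9 lay at a gene end, with folds of 9.75 to 11.3. They included the ends of Klhl7 (chromosome 5, 24100382 to 24100734, fold 11.3, pileup 57), Acat1, a mitochondrial acetyl-CoA enzyme (chromosome 9, 53609994 to 53610533, pileup 62), Pars2, Slc27a4, Rfc3, Katnbl1, BC055324, Clasrp and Actr6. The other lay 12390 bp from Ccr9, a chemokine receptor gene. Of the top 10 H1C-only regions, with folds of 5.00 to 7.56, 1 lay at a gene end, that of Snf8. The strongest, at chromosome 4, 34935748 to 34935989, had a pileup of 40 and lay 13085 bp from Mob3b. The others lay nearest to Rab12, Cyp2b19, Atg10, Fhl2, Arsb, Vmn2r115, Fndc3b and Plcl1. Over all 1949 H1C-only regions, 7.03% (95% interval 5.93 to 8.26) lay at gene ends, against 3.47% after random placement, and their median pileup was 19. The top 5 shared regions were the same in both lists and lay nearest to Chl1, Rab10, Rpusd4, Pex2 and Tcp10c. Near Chl1 (chromosome 6, from 103648964) the pileup was 231 in control and 229 in H1C. It was 187 and 187 near Rab10, 313 and 314 near Rpusd4, 215 and 191 near Pex2, and 179 and 202 near Tcp10c. In the control list these regions lay 29190 to 281679 bp from the nearest gene end. They were below the high-copy bound and so counted among the strong regions. No filter for repeated or poorly mapped sequence was applied here.

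At the level of genes, 7288 of the 10264 protein-coding genes with a control gene-end region also had one in H1C (71.0%, 95% interval 70.1 to 71.9). Control alone had 2976 such genes and H1C alone had 63. Stem cell regulators were kept at 7 of 20 genes (35.0%, 15.4 to 59.2), percentile 23.7 of matched random lists. Gfi1b, a repressor of blood lineage genes (pileup 32), Kit, the stem cell factor receptor (pileup 24), and Meis1, a homeobox factor (pileup 24), had a gene-end region in control only. Mllt3 was kept with pileups of 70 and 33 (log2 ratio -1.23, -1.87 to -0.61). The 7 kept stem cell genes had a median log2 ratio of -1.20, at percentile 0.11 of matched lists. It was the lowest such percentile among the lists with a ratio, and 17 lists were examined with up to 2 percentiles each. A ratio exists only where an H1C region was called, which holds up the ratio of weak regions. Without high-copy regions, the median ratio of shared regions was 0.02 at control pileups up to 20 and -0.90 above 80. Random lists were matched on control fold over all listed genes, not on the pileups of kept genes. The percentile therefore cannot tell a greater loss at stem cell genes from a difference in pileup.

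Genes of DNA repair, replication and the cell cycle mostly kept their gene-end regions. Fanconi anemia and crosslink repair genes were kept at 19 of 25 (76.0%, 54.9 to 90.6; percentile 6.51). Fancf had the strongest control-only region of that list (chromosome 7, 51862146 to 51862453, fold 9.42, pileup 57), followed by Fanci (pileup 35) and Fancg (pileup 31). Rfwd3, a ubiquitin ligase of crosslink repair, was kept with pileups of 78 and 39 (log2 ratio -1.14, -1.74 to -0.57), and Fancl with 56 and 29. Replication fork genes were kept at 39 of 43 (90.7%, 77.9 to 97.4; percentile 89.4). The clamp loader gene Rfc3 (pileup 58), the polymerase gene Pola1 (37) and the primase gene Prim1 (23) had a gene-end region called in control only. Rpa3, a subunit of the protein that coats single-stranded DNA, was kept with pileups of 100 and 47 (log2 ratio -1.23, -1.76 to -0.72), and Hltf with 73 and 40. Cell cycle genes were kept at 20 of 26 (76.9%, 56.4 to 91.0; percentile 92.8), with Ccnb2, Rbl1 and Ccnd2 in control only, Plk1 in H1C only (pileup 23), and Ccna2 (87 and 60) and E2f1 (99 and 48) kept. The p53 response genes were kept at 17 of 21 (81.0%, 58.1 to 94.6; percentile 74.8), with Ei24, Zmat3 and Phlda3 in control only and Polk (97 and 60) and Ccng1 (83 and 45) kept.

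Chromatin, stress and widely expressed genes were also mostly kept. Linker histone genes were kept at 5 of 6 (83.3%, 35.9 to 99.6; percentile 96.7), with H1f1 in control only and H1f4 at pileups of 58 and 44. DEK, histone chaperone and chromatin regulator genes were kept at 33 of 37 (89.2%, 74.6 to 97.0; percentile 94.2). Atrx, Kat5 and Hmgn3 were in control only, and Hmgb2 (107 and 80) and Asf1b (93 and 50) were kept. Interferon and inflammatory genes were kept at 14 of 18 (77.8%, 52.4 to 93.6; percentile 97.6), with Oasl2, Psmb8 and Irf7 in control only and Stat2 (88 and 48) and Stat3 (107 and 69) kept. Heme and oxidative stress genes were kept at 11 of 14 (78.6%, 49.2 to 95.3; percentile 73.7), with Nqo1, Keap1 and Foxo1 in control only and Atm (94 and 61) and Sod2 (76 and 41) kept. Ribosomal protein genes were kept at 66 of 73 (90.4%, 81.2 to 96.1; percentile 99.8), with Rps4x and Rpl26 among those in control only and Rpl27 and Rpl15 kept. Common housekeeping genes were kept at 19 of 21 (90.5%, 69.6 to 98.8; percentile 94.6), with Pgk1 and Hprt kept and Gusb in control only. Cfl1 also counted as control only, although an H1C region overlapped its control region outside the window.

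**Figure D4:**
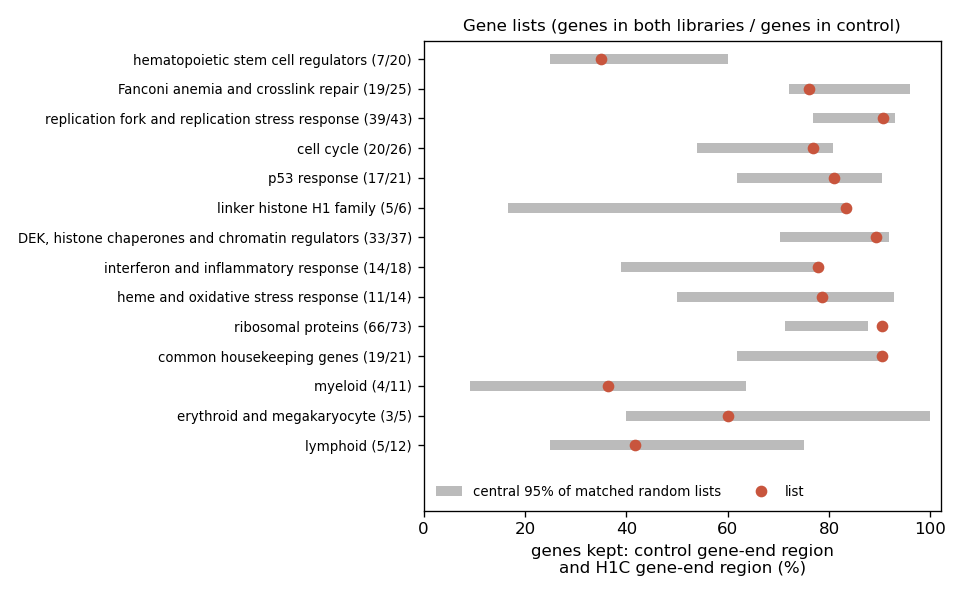
Share of genes with a control gene-end region that also had one in H1C (horizontal axis, %) for each gene list or marker list with at least 5 such genes (red points), with the central 95% of matched random lists (grey bars) and the counts behind each share. Ribosomal proteins lie above their bar at 90.4%, and stem cell regulators lie inside theirs at 35.0%.

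Markers of other cell types were kept at shares inside the range of matched random lists, but the small lists had very wide ranges. The central 95% ran from 0 to 100% for non-hematopoietic, 0 to 50% for endothelial and stromal and 50 to 100% for mast cell markers (2 genes each). It ran from 40 to 100% for the 5 erythroid and megakaryocyte genes. A share inside such a range says little about these 4 lists. Myeloid markers were kept at 4 of 11 genes (36.4%, 10.9 to 69.2; percentile 54.6), with Irf8 and Camp in control only, Fcgr3 counted so although an overlapping H1C region lay outside the window, and Csf2ra and Cebpa kept. Erythroid and megakaryocyte markers were kept at 3 of 5 (percentile 51.1), with Epor and Cd9 in control only and Tfrc and Nfe2 kept. Lymphoid markers were kept at 5 of 12 (41.7%, 15.2 to 72.3; percentile 30.2), with Cd3e, Il7r and Cd79b in control only and Cd3d (69 and 35) and Cd79a (63 and 27) kept. Mast cell and basophil markers were kept at 1 of 2 (percentile 27.4), with Mitf kept and Il1rl1 in control only. Endothelial and stromal markers were kept at 0 of 2 (Kdr and Cdh5; percentile 36.5), and non-hematopoietic markers at 0 of 2 (Cdh1 and Epcam; percentile 29.7). The median log2 ratio of lymphoid markers was -1.03 over 5 genes (percentile 4.64), inside the central 95% of matched lists (-1.07 to -0.48). Mitf, the single mast cell gene with a ratio, had -1.40 (95% interval -2.09 to -0.74; percentile 1.74). Myeloid markers had a median of -0.52 (percentile 79.0) and erythroid and megakaryocyte markers one of -0.82 (percentile 55.7). These medians also depend on the control pileups of the genes with a ratio, so they do not rank loss between cell types.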

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

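The test of the sequences outside chromosomes 1 to 19, X and Y was chosen only after the result was seen. These sequences (unplaced, unlocalised or patch) held 144 regions, 1.09% of the H1C list (95% interval 0.924 to 1.29), against 162 regions, 0.506% (0.431 to 0.590), of the control list. They are given because the share, in data left out of the comparisons, was above that in control. Their number was lower in H1C, and the share was higher because the rest of the H1C list was shorter. Their median depth-scaled log2 pileup ratio was 0.03 over 106 shared regions, against -0.79 over all shared regions of the other chromosomes without high-copy regions.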

How the results depend on the processing

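Tests chosen only after the result was seen were those without high-copy regions, within pileup and width bins, with 50 kb flanks, and all those of the pileup ratio. No paired analysis was possible because each group held 1 library. Base composition and motif alternatives were not run. Of 109 alternatives for 33 results, 66 stayed within the interval or quartiles of the value (counts and lengths within 1.5 times) and 43 moved. For those that moved the cause was not tested. A change of sign was seen in 0, but it was possible only for the kept-share difference and the log2 pileup ratio. The other results cannot be negative. A fold of at least 5 left 12116 control and 4396 H1C regions. Windows of 200 bp covered 6.37 and 2.60 Mb. Control median fold was 6.69 in shared regions and 6.50 in a list of equal length. Control regions shared were 26.8% with 50% reciprocal overlap, 31.8% with summits within 200 bp, 36.1% with −log10 q of at least 5 in both lists, 43.1% with that in control alone and 67.3% with lists of equal length. H1C regions shared were 65.5%, 77.8%, 92.0% (strict in both) and 68.9% (equal length). Gene-end shares in control and H1C were 28.4% and 47.3% within 500 bp, 37.9% and 55.9% within 2500 bp, 37.7% and 55.5% with all genes, 30.7% and 49.96% by summit, and 39.1% and 62.6% at the strict threshold; at equal length the order turned, with 56.3% in control. The kept-share difference between gene-end and other regions was 14.1 points in fold bins, 6.40 in pileup and width bins, 33.3 with reciprocal overlap and 37.3 within 2500 bp. Genes kept were 68.7% at the strict threshold. Regions within gene bodies and 50 kb flanks were kept at 48.6% (Fanconi), 49.8% (replication), 37.6% (cell cycle), 43.7% (p53), 48.6% (chromatin), 36.4% (interferon), 48.4% (oxidative stress), 55.6% (ribosomal) and 50.7% (housekeeping). The lists that stayed within their interval had 25.9% (stem cell), 51.9% (linker histone), 38.2% (myeloid), 41.1% (erythroid and megakaryocyte), 36.7% (lymphoid), 27.8% (mast cell), 14.3% (endothelial and stromal) and 34.5% (non-hematopoietic). Over all control regions the share was 34.1%. Linker histone genes were kept at 100% within 2500 bp. The log2 pileup ratio was -0.70 at strong H1C regions and -0.58 when scaled by the local background at shared summits. Thinned by the ratio of 0.872, 31132 of 31843 control regions still passed the H1C cutoff at the summit, with region width not tested.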

Other observations

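Chosen only after the result was seen were all tests of lower pileups except the number of libraries, both tests of gene-end regions, both tests of lymphoid cells, and the counts within 50 kb of genes. Away from gene ends, within gene bodies and 50 kb on either side, several gene lists held more regions than random lists matched on gene length and density, and these were not limited to blood cell genes. Stem cell regulators held 3.58 per gene in control and 1.22 in H1C (percentiles 99.97 and 99.98), and myeloid markers 3.05 and 1.10 (99.99 and 99.94). Interferon and inflammatory genes held 4.00 and 0.958, and cell cycle genes 3.73 and 1.03. Ribosomal protein genes held 1.96 and 0.645 (99.96 and 99.8) and housekeeping genes 2.88 and 0.917 (99.84 and 98.5). Erythroid and megakaryocyte markers, at 2.39 and 0.667 (93.0 and 78.8), and mast cell markers (27.4 and 40.6) lay inside the random range. Non-hematopoietic markers held 1.18 and 0.353 (37.2 and 39.0), and endothelial and stromal markers 1.80 and 0.133 (47.4 and 2.27).

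Pileups at strong regions were lower in H1C, with a median log2 ratio of -0.92. Lower depth as the whole cause was argued against by a background ratio of 1.10 (log2 0.14), where depth alone would need the unscaled log2 pileup ratio of -0.78. Scaled by the local background at shared summits, which takes in reads of the regions themselves, a drop to -0.58 was left. A wrong depth scale was argued against by a median of -0.12 at high-copy regions, which as the standard left a ratio of -0.80. That standard is loose, with a lower quartile of -0.57 and 50 of 60 control regions shared. It was defined by local background and not by a measured copy number. The SD of the log2 ratio was 0.24 at strong gene-end regions, below the 0.27 to 0.29 of 100 simulations with 1 factor and Poisson counts, and 0.37 away from gene ends (robust SD 0.29), where the highest simulation gave 0.31. These simulations leave out variation between libraries and did not match the noise at gene ends, so whether 1 factor applies to either class stays open. An effect of H1C and a lower yield of the transposase reaction in this library cannot be told apart with 1 library per group.

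Gene-end regions were kept more often than others. Within bins of control pileup a difference of 9.49 points was left (mean over 20 chromosomes, SD 2.55), and within bins of pileup and width 6.36 points (SD 2.58). Both matched differences were above 0 on 20 of 20 chromosomes, which come from the same 2 libraries and are not replicates. The bins rest on a noisy pileup from 1 control library, so a true difference in pileup can remain within them. The matching therefore cannot exclude higher pileup or greater width as the whole cause. Most of the unmatched 42.2 points went with these properties, and no biological explanation was tested, since promoters could not be told from other gene ends here.

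Lymphoid loci were looked at as a possible sign of other cells, although the LSK sort takes lineage-negative cells and would remove mature lymphoid cells, with 3.68 regions per gene in control and 1.04 in H1C. On the lists fixed beforehand the lymphoid loci showed no clear excess over stem cell loci, with ratios of 1.03 in control and 0.851 in H1C, so the condition set for lymphoid cells in both libraries was not met. Gene length and density may account for the lymphoid count in H1C, at percentile 97.05 of matched lists, but the control percentile was 99.93, no higher than that of ribosomal protein genes at 99.96. After these values were seen, a stem cell list without factors shared with other lineages was tried, and its control percentile was 72.1. It met the bound set for it, but its 21 genes were picked with their values in view, so it decides nothing.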
